A study of Oryza sativa with 51 samples.

How the data were processed

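The series holds 51 rice samples in 17 groups of 3 from plants at the 4-leaf stage. RNA was measured in 9 Zhonghua11 samples, 3 each under normal water, moderate drought (relative soil water content of about 20%) and severe drought (about 10%). Monoubiquitinated histone H2B (H2Bub1) was measured by chromatin immunoprecipitation and sequencing (ChIP) in 21 samples, with 21 matching input samples. Of these 42 samples, 18 were from the same Zhonghua11 conditions and 24 from wild type and osbzip46 mutant plants under normal water and drought. Groups and replicate numbers were taken from the labels. Nothing in the labels says that replicates came from separate plants or plantings, so p-values measure only the spread between these samples, which may be technical.

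The RNA tables give 1 value per gene and library. Per the file headers, the authors gave each gene a TPM value (transcripts per 1000000, summing to 1000000 in each library), an FPKM value (fragments per kilobase and per 1000000 fragments) and a coverage (mean read depth per base, not scaled for depth). HISAT2 2.0.5 and DESeq2 1.20.0 are named in the submitters' processing notes with no role, and the program that wrote the RNA tables is not given in the sources used here. The H2Bub1 values came from the authors' deposited tables of comparisons, which combine replicates into 1 value per condition. Per the file headers, these tables hold a log2 concentration per condition and region, a log2 fold change, a p-value and a false discovery rate (FDR). The deposited log2 fold change equalled the difference of both log2 concentrations within 0.01. The p-values and FDR values of regions are the authors' own, computed by a method not given in the sources used here. Bowtie2 2.3.4 and MACS2 2.1.1 are named in the submitters' processing notes, without a role. A further table lists genes with an H2Bub1 log2 fold change between the osbzip46 mutant and wild type under drought, a p-value, a yes or no entry for OsbZIP46 targets and a log2 fold change of expression, per the file headers. Single ChIP and input libraries were not analysed here. The genome build is not given in the sources used here, and coordinates are as the files give them.

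Each RNA library lists 55986 genes. The number of aligned bases was implied by the ratio of coverage to FPKM, taken as its largest value over genes with FPKM over 1. It was 8.30 to 10.7 Gb per library, and read counts were not used here. The design fixed beforehand named a count test for count tables and limma for TPM, so limma was used. Values were analysed as log2(TPM + 1), a scale that understates the change of genes with low values. Genes with at least 1 TPM in at least 3 libraries, 20642 in number, were tested in 1 fit over all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust settings, statmod 1.5.0). Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all tested genes as the threshold. Rose, fell and changed refer to genes past that threshold. Tested on simulated data with 200 changed genes among the 20642, the fit for moderate drought recovered 23.9%, 89.6% and 97.0% of genes changed by 0.5, 1 and 2 on the log2 scale, and called 0.0734% of unchanged genes. The fit for severe drought recovered 23.9%, 82.1% and 100%, with 0.0342% of unchanged genes called. For severe against moderate drought the shares were 16.4%, 86.6% and 100%, with 0.0245% of unchanged genes called. The adjusted threshold loosens as more genes change, so these shares do not carry over to comparisons with far more changed genes. The changed genes were drawn only from those at about 5 TPM or more under normal water. Every simulated library had the same spread per gene, so none stood apart from its group. The shares therefore do not cover genes with lower values or a group with an outlying library.

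The 15 gene lists were fixed before the data were examined. They covered core abscisic acid (ABA) signalling, ABA synthesis and breakdown, ABA-related bZIP factors, stress NAC and DREB factors, drought effectors, H2B ubiquitination enzymes, MODD, antenna proteins with the Rubisco small subunit, chlorophyll breakdown, scavenging of reactive oxygen, the circadian clock, root markers, meristem markers, pathogen response markers and reference genes. The 11 lists with at least 3 tested members were tested against all other genes with camera in limma, with a preset correlation of 0.01 between genes and adjustment over lists. Further lists to be drawn from gene descriptions were not formed, because the tables used here pair no descriptions with the genes. From each list the text names up to 4 members past the threshold with the largest absolute change, and bZIP46, HUB1, HUB2, MODD and the reference genes whatever their result. The 6 largest changes in each direction were also taken, among list genes only. These had a mean of at least 5 TPM in the higher condition and no overlap between the libraries of both conditions. Genes outside the lists are given by identifier, at most 2 in each direction, except where a count of 5 or fewer is listed in full. From each H2Bub1 table the rule took the 5 largest folds in each direction and every list gene with a region. Those 5 largest are described together. Names were checked against a RefSeq gene table (assembly ASM3414082v1) by symbol and by position within 5 Mb on the same chromosome. Of the 105 list genes, 74 had their name at such a position. The other 31 (29 names not in that table and 2 elsewhere in it) are given by identifier, with the name under which each was listed beforehand. Gene models that overlap another model were marked, since strand use in the quantification is not given in the sources used here. Such overlaps concern 6 of the list genes.

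Regions were compared with bedtools 2.31.1, sharing at least 1 bp. Genes shared between tables were tested with Fisher's exact test, two-sided, with adjustment over 18 tests, first over all 55986 genes and then over the 20642 expressed genes. Gene sets from the H2Bub1 tables were tested in the RNA comparisons with camera, with adjustment over 8 sets. Their medians were ranked among 10000 random sets of the same size matched on mean expression in 20 bins. Differences between sets were tested with 100000 permutations, two-sided. Calls shared by both drought levels were set against 20 simulations of unchanged groups that share 3 control libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

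Alternatives fixed before the data were examined were quantile normalization, median-of-ratios scaling, limma without trend and robust settings, FPKM, no filter, a filter of 5 TPM, a pseudocount of 0.1, a log2 fold threshold of 1, fits of 6 libraries, the replicate number as a block, leaving out each library, an estimated correlation in camera, and other thresholds, overlaps and positions of regions. Added after seeing the data were the median-of-ratios scaling for lists, shared genes and region sets, the shared genes without severe replicate 3, expressed genes as background, and region sets without regions at the lowest concentration of a table.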

Results

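RNA levels were measured in rice seedlings of the line Zhonghua11 under normal water, moderate drought and severe drought, with 3 libraries per condition. H2Bub1, a histone mark set by the HUB1 and HUB2 ubiquitin ligases, was compared in the authors' deposited tables between the same conditions, and between osbzip46 mutant and wild type plants. OsbZIP46 is a transcription factor of the abscisic acid (ABA) pathway. Each RNA library listed 55986 genes, of which 19185 to 20012 had at least 1 TPM, and implied 8.30 to 10.7 Gb of aligned bases. No pair of libraries held identical values. Libraries correlated at 0.990 or more within the normal group and at 0.989 or more within the moderate group, and severe replicates 1 and 2 at 0.993. Severe replicates 1 and 2 correlated with moderate libraries at 0.986 to 0.992, against 0.989 to 0.992 within the moderate group. Severe replicate 3 stood apart, with a correlation of at most 0.955 with any other library.

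**Figure D1:**
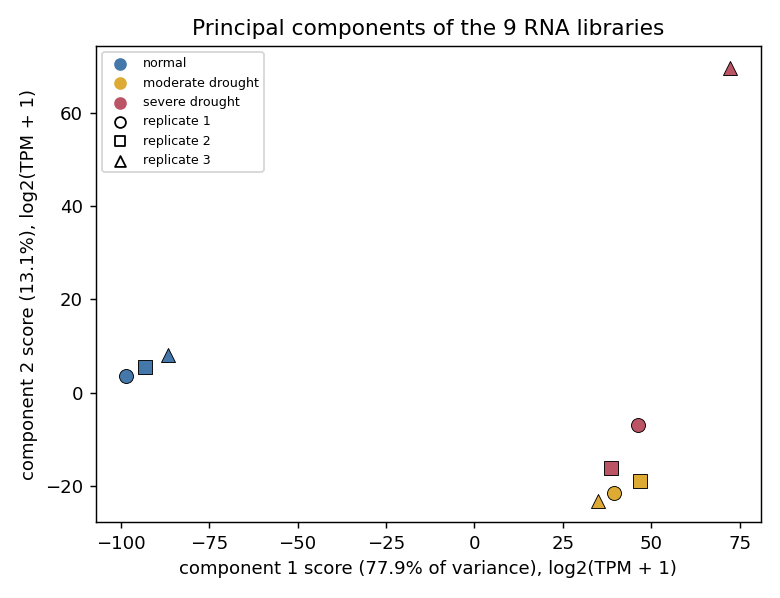
Principal components of log2(TPM + 1) in the 9 RNA libraries. Each point is a library, with color for the condition and shape for the replicate number. Component 1 (77.9% of the variance) separates the 3 normal libraries from the 6 drought libraries, and component 2 (13.1%) sets severe replicate 3 apart.

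Moderate drought was compared with normal water to find the genes that respond to drying soil. Genes for some stress proteins rose in RNA from low levels. RAB16A, a dehydrin gene, had 1.17 TPM ± 0.833 (SD, n = 3) under normal water and 422 TPM ± 156 under moderate drought, and LEA3-1, a late embryogenesis abundant protein gene, had 0.464 TPM ± 0.270 and 308 TPM ± 64.6. Most phosphatase genes that hold ABA signalling in check rose too, among them PP2C51 from 0.653 TPM ± 0.260 to 49.4 TPM ± 3.13. The Rubisco small subunit gene RbcS (LOC_Os12g17600) fell from 8226 TPM ± 1359 to 1992 TPM ± 287, and 7 of 9 clock genes fell.

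In all, 12040 of the 20642 tested genes changed in moderate drought, 8133 higher and 3907 lower, and 3995 of them by at least 1 on the log2 scale. The fit shares 1 error per gene over all 9 libraries, severe replicate 3 among them, and a fit of the 6 libraries compared called 13996 genes. The median log2 fold change of all tested genes was 0.20, so 67.6% of changed genes were higher. After quantile normalization 5690 were higher and 5780 lower, and after median-of-ratios scaling 5744 and 5826, so the balance between higher and lower genes rests on the scaling. Folds of single genes are given as fitted, and list medians also less the median of all genes. The 3 libraries of one condition lay beyond the 3 of the other in 73.1% of genes, where chance gives 10%.

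In core ABA signalling, 12 of 22 tested genes rose, 6 fell and 4 were not called, with the same counts adjusted over the list alone. PP2C51 rose by 4.94 ± 0.32 (SE, log2), PP2C68 by 3.58 ± 0.30, PP2C49 by 3.29 ± 0.18 and PP2C30 by 2.74 ± 0.20. The kinase gene SAPK9 fell by 2.08 ± 0.39, and its model overlaps another on the opposite strand. LOC_Os03g18600, listed beforehand as the receptor PYL6, fell by 1.87 ± 0.20. The list median was 0.64 (0.44 above the median of all genes; camera adjusted p = 0.532), and 0.42 after quantile normalization or median-of-ratios scaling. Among genes of ABA synthesis and breakdown, 3 rose and 2 fell of 7, as they did adjusted over the list alone. NCED3, which encodes a carotenoid-cleaving enzyme of ABA synthesis, rose by 2.47 ± 0.24, and LOC_Os07g05940, listed beforehand as NCED4, by 3.62 ± 0.38. LOC_Os12g42280, listed beforehand as NCED5, fell by 2.65 ± 0.15, and the ABA-degrading enzyme gene ABA8ox1 rose by 1.58 ± 0.42. The mean of this list was 0.57, while its median (−0.07, −0.31 after quantile normalization and 0.12 without moderate replicate 2) and the camera direction were negative (adjusted p = 0.733).

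All 5 tested ABA-related bZIP genes rose, also adjusted over the list alone, with a median of 1.64 (1.44 above that of all genes; camera adjusted p = 0.039, adjusted p = 0.414 with an estimated correlation). bZIP23 rose by 2.56 ± 0.16, LOC_Os01g64730 (listed beforehand as ABF1) by 2.24 ± 0.25 and LOC_Os06g10880 (listed beforehand as bZIP46) by 1.64 ± 0.12. LOC_Os06g10880 went from 2.68 TPM ± 0.398 to 10.4 TPM ± 1.14. TRAB1 rose by 0.46 ± 0.13, a call that ended under quantile normalization (adjusted p = 0.0733) and median-of-ratios scaling (adjusted p = 0.14), and without normal replicate 1 (0.0558) or moderate replicate 3 (0.0521). Of 8 stress NAC and DREB genes, 2 rose and 1 fell, as adjusted over the list alone (median 0.64, 0.44 above that of all genes; camera adjusted p = 0.733). LOC_Os11g03300, listed beforehand as NAC10, rose by 4.31 ± 0.14 and NAC5 by 0.91 ± 0.12, while DREB1A, a factor of cold responses, fell by 2.53 ± 0.41.

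Of 12 drought effector genes, 7 rose, 1 fell and 4 were not called, against 9 risen and 1 fallen adjusted over the list alone. LEA3-1 rose by 7.72 ± 0.56, RAB16A by 7.63 ± 0.77, RAB16B by 5.44 ± 0.88 and SalT, a salt-induced lectin, by 5.20 ± 0.74. TPP1, a trehalose phosphate phosphatase gene whose model overlaps another on the same strand, fell by 2.41 ± 0.10. The list median was 2.35, 2.15 above that of all genes. Its camera adjusted p was 0.0784, and it passed the threshold after quantile normalization (adjusted p = 0.0146) and median-of-ratios scaling (adjusted p = 0.0142), but not with an estimated correlation (adjusted p = 0.8).

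Antenna and Rubisco genes lay lower, with 4 of 14 past the threshold and none higher, also adjusted over the list alone (median −0.74, −0.94 relative to all genes; camera adjusted p = 0.00233, adjusted p = 0.771 with an estimated correlation and 0.259 after quantile normalization). Errors are shared over all 9 libraries, so the spread of severe replicate 3 widens them here too, and the count of 4 may be low. LOC_Os07g37240 (listed beforehand as CP29) was at −1.02 ± 0.41 (adjusted p = 0.0595 in limma). Its normal libraries lay at 4465 to 6078 TPM and its moderate ones at 2302 to 2818 TPM. RbcS fell by 2.04 ± 0.38 at LOC_Os12g17600, by 1.77 ± 0.20 at LOC_Os12g19470 and by 1.38 ± 0.27 at LOC_Os12g19381, and the antenna gene CAB2R fell by 1.83 ± 0.25. In the circadian clock, 7 of 9 genes fell, also adjusted over the list alone (median −0.70, −0.90 relative to all genes; camera adjusted p = 0.00233, adjusted p = 0.414 with an estimated correlation). LHY fell by 0.83 ± 0.20, PRR73 by 0.75 ± 0.11, PRR37 by 0.71 ± 0.11 and LOC_Os11g34460, listed beforehand as FKF1, by 0.70 ± 0.10.

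Of 3 chlorophyll breakdown genes, LOC_Os03g05310 (listed beforehand as PAO) rose by 1.26 ± 0.26, with 2 risen and 1 fallen adjusted over the list alone (median 1.26, 1.06 above that of all genes; camera adjusted p = 0.884). Of 5 genes that scavenge reactive oxygen, the ascorbate peroxidase gene APX1 rose by 0.83 ± 0.09 and the catalase gene CatA fell by 0.98 ± 0.20, as they did adjusted over the list alone. The median of that list was 0.15 and its mean 0.03, while the camera direction was down (adjusted p = 0.733), as was the median relative to all genes (−0.05). After quantile normalization the median was 0.29 and after median-of-ratios scaling −0.08. Of the H2B ubiquitination enzymes, HUB2 fell by 0.27 ± 0.08 (adjusted p = 0.0194 in limma) and HUB1 was not called at −0.06 ± 0.10, with 1 fallen adjusted over the list alone and a list median of −0.16. HUB1 passed the threshold as lower under quantile normalization (adjusted p = 0.0314) and median-of-ratios scaling (adjusted p = 0.0183), and leaving out normal replicate 3 or moderate replicate 2 gave 0.02. HUB2 was at −0.47 and −0.50 after these scalings (adjusted p = 0.000582 and 0.000519), but lost its call in 3 of 6 fits with a library left out, without normal replicate 3 (adjusted p = 0.0602), moderate replicate 1 (0.0645) or moderate replicate 2 (0.0679). MODD, a gene of the OsbZIP46 pathway, was at 0.79 ± 0.32 (adjusted p = 0.0625) and passed adjusted over the list alone, where it is the single member. In the fit of the 6 libraries compared MODD passed the threshold (adjusted p = 0.000137).

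The labels do not name the tissue of the RNA samples. Of 3 tested root markers, 1 rose and 2 fell, also adjusted over the list alone (median −0.50, −0.70 relative to all genes; camera adjusted p = 0.532). The transporter gene HKT2;1 rose from 0.114 TPM ± 0.0294 to 2.23 TPM ± 0.325, IRT1 fell from 1.65 TPM ± 0.199 to 0.272 TPM ± 0.0992 with a model that overlaps another on the opposite strand, and Lsi1 fell by 0.50 ± 0.17 with adjusted p of 0.0281 in limma, lost without a filter (adjusted p = 0.0565) and when any of 5 of the 6 libraries was left out (adjusted p of 0.0556 to 0.093). Neither meristem marker passed the expression filter. Of the pathogen response markers only PBZ1 passed the filter, at 0.48 ± 0.57 (adjusted p = 0.492), with none called adjusted over the list alone. The 3 reference genes all rose, also adjusted over the list alone, by 1.66 ± 0.12 at LOC_Os01g22490 (listed beforehand as UBQ5), 0.94 ± 0.10 at ACT1 and 1.51 ± 0.12 at LOC_Os03g08020 (listed beforehand as eEF1A). Their median lay 1.31 above that of all genes (camera adjusted p = 0.039, adjusted p = 0.414 with an estimated correlation).

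The largest rise of any gene with at least 5 TPM belonged to LOC_Os01g68290 (chromosome 1, 39679524 to 39680147), from 1.21 TPM ± 1.12 to 1005 TPM ± 193. The largest fall was at LOC_Os05g49240 (chromosome 5, 28253514 to 28255081), from 1232 TPM ± 62.5 to 0.994 TPM ± 0.252, in a model that overlaps another on the opposite strand.

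**Figure D2:**
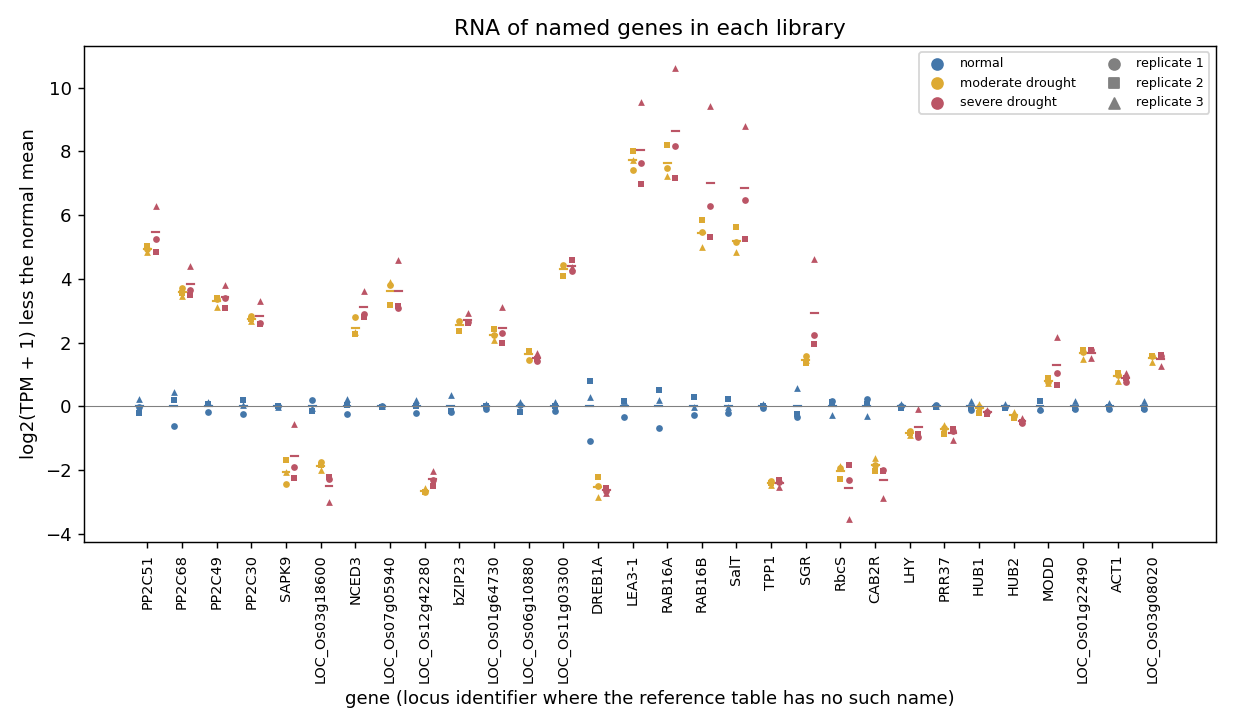
RNA of named genes as log2(TPM + 1) less the mean of the normal libraries. Each point is a library, with color for the condition and shape for the replicate number, and bars are the means of 3 libraries. LEA3-1 and RAB16A lie on average 7.63 to 8.66 above normal in both droughts, and severe replicate 3 lies apart from the other severe libraries at RAB16B, SalT and SGR.

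Severe drought against normal water addressed the same question at about 10% relative soil water. RAB16A was at 1363 TPM ± 1596 (SD, n = 3) against 1.17 TPM ± 0.833 under normal water, and SalT at 293 TPM ± 343 against 0.536 TPM ± 0.230. Antenna genes fell widely, as CAB2R did from 5012 TPM ± 912 to 1031 TPM ± 314. SGR, which starts chlorophyll breakdown, rose from 19.5 TPM ± 7.57 to 216 TPM ± 230. The wide errors come with severe replicate 3, where RAB16A was at 3198 TPM, against 597 and 295 TPM in severe replicates 1 and 2.

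In severe drought 12942 genes changed, 8687 higher and 4255 lower, and 4479 of them by at least 1 on the log2 scale. Without severe replicate 3 there were 13807, 9162 higher and 4645 lower. The median of all genes was 0.22, and 67.1% of changed genes were higher. After quantile normalization 5909 were higher and 6317 lower, and after median-of-ratios scaling 6223 and 6118. The libraries of both conditions did not overlap in 68.6% of genes.

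In core ABA signalling, 12 of 22 genes rose and 6 fell, also adjusted over the list alone (median 0.75, 0.53 above that of all genes; camera adjusted p = 0.317). PP2C51 rose by 5.46 ± 0.32, PP2C68 by 3.85 ± 0.30, PP2C49 by 3.42 ± 0.18 and PP2C30 by 2.84 ± 0.20, and LOC_Os03g18600 (listed beforehand as PYL6) fell by 2.51 ± 0.20. Of 7 genes of ABA synthesis and breakdown, 3 rose and 3 fell, against 3 and 4 adjusted over the list alone. NCED3 rose by 3.11 ± 0.24, LOC_Os07g05940 (listed beforehand as NCED4) by 3.62 ± 0.38 and ABA8ox1 by 1.57 ± 0.42, while LOC_Os12g42280 (listed beforehand as NCED5) fell by 2.28 ± 0.15. The list's mean of 0.52 again opposed a median of −0.61 and a downward camera direction (adjusted p = 0.4), and without severe replicate 3 the median was −0.33.

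Of 5 ABA-related bZIP genes 4 rose, also adjusted over the list alone, with bZIP23 up by 2.72 ± 0.16, LOC_Os01g64730 (listed beforehand as ABF1) by 2.47 ± 0.25 and LOC_Os06g10880 (listed beforehand as bZIP46) by 1.53 ± 0.12. TRAB1 rose by 0.42 ± 0.13, not past the threshold under quantile normalization (adjusted p = 0.219) or median-of-ratios scaling (adjusted p = 0.213), in the fit of 6 libraries (0.0508), or without normal replicate 1 (0.0742) or normal replicate 2 (0.05). Without severe replicate 3 it was at 0.26. The list median of 1.53 (1.31 above that of all genes) had a camera adjusted p of 0.0501, or 0.453 with an estimated correlation. It fell to 0.0323 after quantile normalization, 0.0405 after median-of-ratios scaling and 0.0467, 0.0461 and 0.0453 without severe replicate 3, normal replicate 2 or normal replicate 3. Of 8 stress NAC and DREB genes, 5 rose and 2 fell, also adjusted over the list alone (median 0.96, 0.74 above that of all genes, and 0.61 without severe replicate 3; camera adjusted p = 0.584). LOC_Os11g03300 (listed beforehand as NAC10) rose from 0.572 TPM ± 0.152 to 32.2 TPM ± 3.98 and DREB1C by 2.33 ± 0.56. DREB1A fell by 2.65 ± 0.41 and DREB1B by 2.43 ± 0.76, a call that ended without severe replicate 1 (adjusted p = 0.053), severe replicate 3 (0.0873), normal replicate 2 (0.0763) or normal replicate 3 (0.0755).

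Of 12 drought effector genes 10 rose and 1 fell, also adjusted over the list alone (median 2.53, 2.31 above that of all genes; camera adjusted p = 0.0398, adjusted p = 0.769 with an estimated correlation). RAB16A rose by 8.66 ± 0.77, LEA3-1 by 8.06 ± 0.56, RAB16B by 7.01 ± 0.88 and SalT by 6.85 ± 0.74, while TPP1 fell by 2.40 ± 0.10 (its model overlaps another on the same strand). Severe replicate 3 had 1129 TPM of RAB16B against 126 and 63.3 TPM in severe replicates 1 and 2. Antenna and Rubisco genes fell in 12 of 14 cases, or 13 adjusted over the list alone (median −1.33, −1.55 relative to all genes; camera adjusted p = 5.01e-05, adjusted p = 0.616 with an estimated correlation). That median was −0.81 without severe replicate 3. RbcS fell by 2.58 ± 0.38 at LOC_Os12g17600 and fell by 1.88 ± 0.20 at LOC_Os12g19470, and CAB2R by 2.32 ± 0.25. LOC_Os11g13890 (listed beforehand as CP26) fell by 1.80 ± 0.46, and was at −1.16 without severe replicate 3.

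In the circadian clock 6 of 9 genes fell, also adjusted over the list alone (median −0.58, −0.80 relative to all genes; camera adjusted p = 0.00186, adjusted p = 0.453 with an estimated correlation). PRR73 fell by 0.91 ± 0.11, PRR37 by 0.86 ± 0.11, LOC_Os11g34460 (listed beforehand as FKF1) by 0.72 ± 0.10 and LHY by 0.65 ± 0.20. LHY lost its call in the fit of 6 libraries (adjusted p = 0.0519) and without normal replicate 1 (0.0533), normal replicate 3 (0.0597), severe replicate 1 (0.0688) or severe replicate 2 (0.0641). Of 3 chlorophyll breakdown genes, SGR rose by 2.93 ± 0.61 and LOC_Os03g05310 (listed beforehand as PAO) by 1.39 ± 0.26, also adjusted over the list alone (median 1.39, 1.17 above that of all genes; camera adjusted p = 0.584). SGR was at 481 TPM in severe replicate 3 and at 91.2 and 74.7 TPM in the other two. Of 5 genes that scavenge reactive oxygen, APX1 rose by 0.93 ± 0.09 while CatA fell by 0.62 ± 0.20 and LOC_Os03g03910 (listed beforehand as CatC) by 0.57 ± 0.18, also adjusted over the list alone. CatA was at −0.40 without severe replicate 3 and lost its call without normal replicate 2 (adjusted p = 0.0891) or normal replicate 3 (0.0843), without a filter (0.0509) and in the fit of 6 libraries (0.056). LOC_Os03g03910 was at −0.01 after quantile normalization (adjusted p = 0.949), and lost its call without normal replicate 3 (0.0713) and in the fit of 6 libraries (0.0512). The median of this list was −0.44 and its camera direction down (adjusted p = 0.584), with a mean of 0.02. The median was 0.06 without severe replicate 3, −0.01 after quantile normalization and −0.67 after median-of-ratios scaling.

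HUB2 fell by 0.47 ± 0.08 (by 0.71 after quantile normalization) and HUB1 was at −0.19 ± 0.10 (adjusted p = 0.134), past the threshold as lower under quantile normalization (adjusted p = 0.00228) and median-of-ratios scaling (0.00261), with 1 of the 2 enzymes called also adjusted over the list alone. MODD rose by 1.28 ± 0.32, also adjusted over the list alone, and by 0.85 without severe replicate 3. Of 3 tested root markers 1 rose and 1 fell, also adjusted over the list alone (median −0.14, 0.02 without severe replicate 1 and −0.41 after quantile normalization, mean 0.05, camera direction down with adjusted p = 0.584), with HKT2;1 at 1.48 ± 0.16 and IRT1 at −1.20 ± 0.11. No meristem marker passed the filter, and PBZ1, the 1 pathogen marker tested, was at 0.44 ± 0.57 (adjusted p = 0.519), also not called adjusted over the list alone. The 3 reference genes rose, also adjusted over the list alone, by 1.68 ± 0.12 at LOC_Os01g22490 (listed beforehand as UBQ5), 0.88 ± 0.10 at ACT1 and 1.48 ± 0.12 at LOC_Os03g08020 (listed beforehand as eEF1A). Their median lay 1.26 above that of all genes (camera adjusted p = 0.0493, adjusted p = 0.453 with an estimated correlation, 0.0503 with a pseudocount of 0.1 and 0.0514 without severe replicate 2). LOC_Os01g68290 again rose most among genes with at least 5 TPM, by 9.67 ± 0.41 to 1697 TPM ± 621, and the largest fall was again at LOC_Os05g49240, which fell by 9.39 ± 0.14.

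Both drought levels changed largely overlapping sets of genes. There were 7324 genes that rose in both and 3486 that fell in both, where independent lists would share 3423 and 805. Another 1228 genes were called in moderate drought only and 2130 in severe drought only, and 2 genes went opposite ways. Fold changes correlated at 0.948 across genes, which are not independent replicates, and 89.9% had the same sign. Unchanged simulated groups against 3 shared controls gave 0.497 and 66.5%, and shared no calls. The covariance was 0.872 against 0.019 in simulation, a difference of 0.853. The simulated covariance, at most 0.021, argues against the spread between the normal libraries as the main source of the observed one. A shift common to all 3 normal libraries was not simulated. Only 3 normal libraries exist in the comparison, too few to split, so part of the excess may come from such a shift. Without severe replicate 3 the shared genes numbered 12645, of which 8518 rose and 4127 fell in both.

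Severe drought was compared with moderate drought to find what differs between the levels. With 3 libraries each, 3 genes passed the threshold in limma, and 2582 had an unadjusted p under 0.05. These 3 genes are named because they are all that passed, after their values were seen. LOC_Os03g16140 (chromosome 3, 8902704 to 8906354) rose from 22.5 TPM ± 2.13 (SD, n = 3) to 50.2 TPM ± 7.73, with 34.8 TPM ± 1.51 under normal water. LOC_Os08g02210 (chromosome 8, 751274 to 753264) fell from 134 TPM ± 4.95 to 67.1 TPM ± 7.31, with 171 TPM ± 11.6 under normal water. LOC_Os12g37415 (chromosome 12, 22967916 to 22968353) rose from 0.198 TPM ± 0.00906 to 362 TPM ± 80.3, and lies inside the model of LOC_Os12g37410 on the same strand. Their log2 fold changes were 1.11 ± 0.12 (SE; adjusted p = 0.0464), −0.99 ± 0.10 (adjusted p = 0.0464) and 8.22 ± 0.15 (adjusted p = 5.72e-08). After median-of-ratios scaling, without the trend and robust settings, or without a filter, 1 gene passed.

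Antenna and Rubisco genes were lower in severe than in moderate drought as a list (median −0.52, −0.51 relative to all genes; camera adjusted p = 0.00253, adjusted p = 0.935 with an estimated correlation), while none of the 14 passed alone or adjusted over the list alone. Without severe replicate 3 that median was −0.10 (adjusted p = 0.47). Drought effectors had a median of 0.85 and camera adjusted p of 0.129, with none called adjusted over the list alone. Without severe replicate 3 their median was 0.04 (adjusted p = 0.994), and without severe replicate 2 it was 1.32 (adjusted p = 0.00293). Core ABA signalling had a median of 0.11 (adjusted p = 0.129), which passed without severe replicate 2 (adjusted p = 0.0137), while without severe replicate 3 the median was 0.00 (adjusted p = 0.994). In the other 8 lists tested with camera the adjusted p was 0.207 or more, and 1 member of ABA synthesis and breakdown was called adjusted over the list alone. LOC_Os06g10880 (listed beforehand as bZIP46), HUB1, HUB2, MODD and the reference genes were not called. MODD was at 0.50 ± 0.32, and at 0.06 without severe replicate 3 or 0.81 without severe replicate 2. Without severe replicate 3, 11 genes passed the threshold, 6 higher and 5 lower, and no list did.

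H2Bub1 differed from normal water at many regions in both droughts, and most of these were lower. The authors' deposited table for moderate drought lists 1395 regions of 500 bp, 224 higher and 1171 lower, at 221 and 1115 genes. Their table for severe drought lists 886, 93 higher and 793 lower, at 90 and 780 genes. Both tables hold only regions with FDR under 0.05 and an absolute log2 fold of at least 1, and the folds are the authors', with no replicate values. How the ChIP values were scaled is not given in the sources used here. The balance between higher and lower regions may rest on that scaling, which was not tested. Higher regions lay nearer to gene starts. Within 1 kb of a transcription start lay 133 of 224 higher regions of the moderate table, against 287 of 1171 lower ones (odds ratio 4.50, Fisher's exact test, two-sided, adjusted p = 5.82e-23). For severe drought the counts were 67 of 93 and 200 of 793 (odds ratio 7.64, adjusted p = 1.53e-18).

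Several ABA genes carried such regions. In the authors' deposited table for moderate drought, H2Bub1 was higher at bZIP23 (chromosome 2, 32280076 to 32280575) with a log2 fold of 1.49 and FDR of 1.08e-09, at PP2C30 with 4.10, at PP2C51 with 6.44 and at SGR with 4.31. The fold at PP2C51 rests on a normal value at the lowest concentration of that table. It was lower at LOC_Os02g15640 (listed beforehand as PYL10) with −1.25 and at SAPK1 with −1.06. In the authors' deposited table for severe drought, H2Bub1 was lower at PP2C06 (−1.12), PP2C08 (−1.59), HUB2 (−1.05) and bZIP23 (−1.17, FDR 0.0173; chromosome 2, 32280132 to 32280631). Thus bZIP23 had a higher region in the moderate table and a lower one, overlapping it, in the severe table, 1 of 6 genes with opposite directions. The largest folds in the authors' deposited tables, 6.80 and −7.48 in moderate and 6.24 and −6.81 in severe drought, and the other 4 largest in each direction, all had 1 condition at the lowest concentration of the table.

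Regions of both drought tables overlapped. Of the authors' 886 severe regions 263 (29.7%) shared at least 1 bp with a moderate region, and 260 of the 263 had the same direction, 15 higher and 245 lower. Since most regions of both tables are lower, unrelated directions would give 202 of 263. The tables shared 281 genes, against 20.7 expected over all genes (odds ratio 24.5, Fisher's exact test, two-sided, adjusted p = 4.08e-238) and 268 against 50.7 over expressed genes (odds ratio 9.04, adjusted p = 7.70e-125). Both tables rest on the same normal ChIP libraries, so part of that overlap may come from the shared controls. Only genes with an H2Bub1 region can enter either table, and no background of such genes was used. Part of the excess of shared genes may come from that as well.

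The RNA of genes with changed H2Bub1 was compared at the same drought level, to ask whether mark and transcript move together. In moderate drought both mostly lay in the same direction. Of 212 tested genes with higher H2Bub1 in the authors' deposited table, 185 rose and 1 fell in RNA, with a median log2 fold change of 1.41 against 0.20 for all genes (camera adjusted p = 2.76e-17, adjusted p = 0.0984 with an estimated correlation). Of 1051 genes with lower H2Bub1, 139 rose and 473 fell, with a median of −0.27 (camera adjusted p = 8.98e-14, adjusted p = 0.201 with an estimated correlation). After median-of-ratios scaling the medians were 1.18 and −0.49, and for lower regions with the larger folds −0.48. Both medians lay outside all 10000 random sets matched on expression, at percentiles 100 and 0.

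In severe drought the relation was smaller. Of 82 tested genes with higher H2Bub1 in the authors' deposited table, 49 rose and 10 fell in RNA, with a median of 0.42 against 0.22 for all genes (camera adjusted p = 0.0297, adjusted p = 0.252 with an estimated correlation, 0.0558 for the regions with the larger folds). Of 748 genes with lower H2Bub1, 231 rose and 218 fell, with a median of 0.04 (camera adjusted p = 0.0193, adjusted p = 0.569 with an estimated correlation). The sign of that median turned after median-of-ratios scaling (−0.17) and for the regions with the larger folds (−0.03), and the median of the higher set was 0.24 after that scaling. These medians lay at percentiles 99 and 0 of random sets. Across genes, which are not independent replicates, the H2Bub1 fold and the RNA fold correlated with Spearman's rho of 0.515 and Pearson's r of 0.68 in moderate drought and with 0.147 and 0.224 in severe drought. Each gene was taken at its region with the largest absolute fold, regions at the lowest concentration included. The tables hold no absolute folds under 1, and 16.1% of moderate and 10.5% of severe regions were higher. These coefficients also depend on that split, so both levels are not directly comparable. Genes found in 1 table only were compared, each table at its own drought level. The median RNA change of genes with higher H2Bub1 was 1.06 greater for the moderate table. That of genes with lower H2Bub1 differed by −0.46. Both differences had an adjusted p of 1e-05 in a two-sided permutation test over genes, the smallest that 100000 permutations can give. The test treats genes as independent, though estimated correlations between genes in these sets were 0.021 to 0.107. The p-value therefore does not measure the spread between libraries and may be too small.

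**Figure D3:**
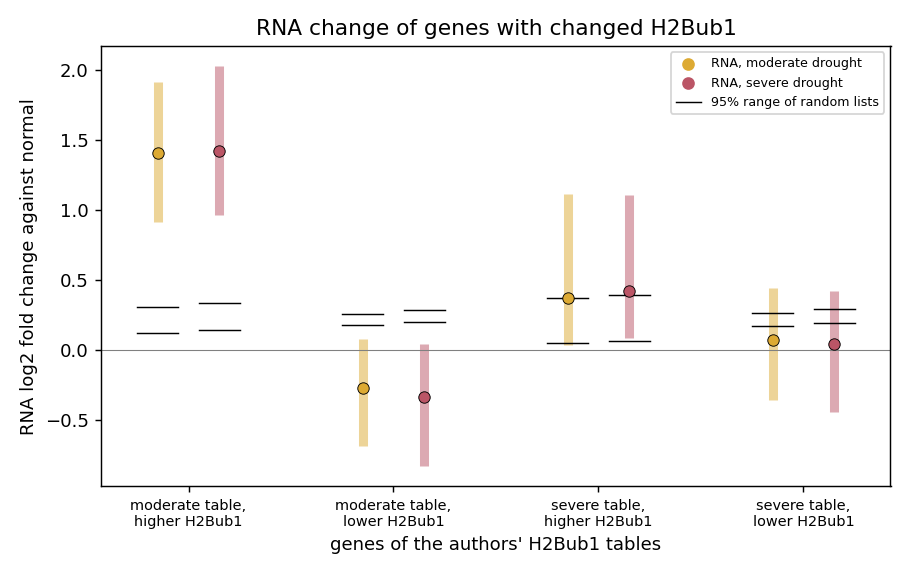
RNA log2 fold change against normal for genes of the authors' H2Bub1 tables. Points are medians, bars run from the first to the third quartile, color gives the RNA comparison, and paired lines enclose 95% of 10000 random gene sets matched on expression. Genes with higher H2Bub1 in the moderate table have medians of 1.41 and 1.42 in both droughts, and those of the severe table have 0.37 and 0.42.

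The osbzip46 experiment compared H2Bub1 between mutant and wild type plants. One of the authors' deposited tables, said to be for drought by its name alone, lists 522 regions, of which 432 were higher in the mutant and 90 lower. Of these 9 had FDR under 0.05 and 255 a p under 0.05, so most pass no adjusted threshold. Among list genes it holds LOC_Os11g05930 (listed beforehand as PRR59; log2 fold 1.47, FDR 0.418), LOC_Os07g37550 (listed beforehand as Lhcb3; 1.14, FDR 0.637) and LOC_Os06g21590 (listed beforehand as Lhca1; 1.38, FDR 0.837). The largest folds in this authors' deposited table were 6.45 at LOC_Os06g03200, with the wild type at the lowest concentration, and −2.88 at LOC_Os05g01280 (FDR 0.509). Within 1 kb of a transcription start lay 203 of 432 higher and 34 of 90 lower regions (odds ratio 1.46, Fisher's exact test, two-sided, adjusted p = 0.13).

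A second of the authors' deposited tables, for drought by its header, lists 1265 genes with lower H2Bub1 in the mutant, with log2 folds from −3.25 to −1, and marks 217 of these genes as OsbZIP46 targets. It gives a p-value from a test not named in the sources used here, at most 0.0499, and no FDR. Whether these genes pass an adjusted threshold is therefore not known. Among the list genes that follow, that p-value ran from 0.000287 (LOC_Os09g28310) to 0.0351 (APX1). It holds LHY (−1.86, a target), LOC_Os09g28310 (listed beforehand as bZIP72; −1.47, a target), PP2C53 (−1.44, a target), P5CS1 (−1.12, a target) and APX1 (−1.30, not a target). Both mutant tables shared 9 genes against 11.6 expected over all genes (odds ratio 0.774, adjusted p = 0.715, Fisher's exact test, two-sided), and 8 against 27.9 over expressed genes (odds ratio 0.269, adjusted p = 3.18e-05). Over expressed genes the second table also shared 29 against 63.1 with lower H2Bub1 in moderate drought (odds ratio 0.431, adjusted p = 3.39e-06). For lower H2Bub1 in severe drought these were 36 against 44.9 (adjusted p = 0.234), and neither set with higher H2Bub1 was called. Over all genes the lower sets shared 32 against 25.2 in moderate and 37 against 17.6 in severe drought. The latter was more than expected (adjusted p = 7.28e-05, same test). The shortfall thus rests on the background used. The first mutant table holds mostly higher regions, few of them at FDR under 0.05, while the second holds lower genes only. Whether the second was cut to 1 direction is not given in the sources used here. It therefore cannot show a direction opposite to the first. Which of them describes the mutant under drought is not settled here. Genes with lower H2Bub1 in moderate drought and higher H2Bub1 in the mutant table of regions numbered 49 against 19.5 expected over expressed genes (odds ratio 2.82, adjusted p = 2.03e-08), and genes lower in both numbered 11 against 4.23 (odds ratio 2.87, adjusted p = 0.00634), so the excess was not limited to opposite directions. Of 28 region pairs of these tables that overlap, 24 were lower in moderate drought and higher in the mutant, where directions unrelated between the tables would give 19.5. Over expressed genes, those with lower H2Bub1 in severe drought and higher H2Bub1 in the mutant numbered 17 against 13.9 (odds ratio 1.24, adjusted p = 0.486, Fisher's exact test). Those lower in both numbered 9 against 3.01 (odds ratio 3.26, adjusted p = 0.00634). Only genes with an H2Bub1 region can enter these tables of regions, and no background of such genes was used. These counts thus cannot tell a link between drought and mutant changes from a shared pool of genes with the mark. Of 12 overlapping pairs of the severe and mutant tables, 8 had the same direction against 2.89 if unrelated, and of 25 within 1 kb 13 did. Of expressed genes marked as targets, 86 of 216 (39.8%) rose in moderate drought, against 495 of 1023 (48.4%) of the other genes in that table (odds ratio 0.706, Fisher's exact test, two-sided, adjusted p = 0.0722). In the expression column of that authors' deposited table, 69 of 217 targets (31.8%) were at 1 or more, against 267 of 1047 other genes (25.5%; odds ratio 1.36, adjusted p = 0.0722).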

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

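The tests in this part were chosen after the results they weigh were seen, except that leaving out each library was fixed beforehand. The RNA change of genes with changed H2Bub1 differed between the authors' tables for both drought levels. Among genes in 1 of the authors' tables only, the median RNA change with higher H2Bub1 was 1.41 in moderate drought (196 genes) and 0.35 in severe drought (66 genes), a difference of 1.06, and with lower H2Bub1 it was −0.27 (803 genes) and 0.19 (500 genes), a difference of −0.46. Each set itself had much the same RNA median at both levels. The moderate sets were at 1.44 (higher) and −0.33 (lower) in severe drought, and the severe sets at 0.255 and 0.188 in moderate drought. The difference thus lay in which genes each table holds. The checks that follow cover the sets with higher H2Bub1 only. The tables argue against severe replicate 3 as the cause there, since the severe median for higher H2Bub1 without it was 0.41, against a lowest value of 1.35 for the moderate set with any library left out. Regions at the lowest concentration were 19 of the 224 higher regions of the moderate table, too few to bring its median down to the severe one. The moderate median of 1.35 without them was therefore no test of their part. The tables argue against a weaker RNA response to severe drought at the genes with higher H2Bub1 in moderate drought only, which had a median of 1.44 in severe drought. The quality and labels of the severe ChIP libraries, which were not analysed here one by one, stay open, as does a biological difference between drought levels, which is untested.

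Severe replicate 3 lay apart from the other severe libraries, with 1736 genes off by more than 1 on the log2 scale against at most 621 in any other library. A shallower library is argued against by its 9.41 Gb of aligned bases, as implied by coverage and FPKM, within the 8.30 to 10.7 Gb of the other 8. Severe replicates 1 and 2 correlated with moderate libraries at 0.986 to 0.992, against 0.989 to 0.992 within the moderate group, and their labels were not tested. For severe replicate 3 a wrong label among the 3 conditions is argued against by its highest correlation of 0.955 with any library. That is under the 0.989 seen within the normal and moderate groups. A further step of the same drought response cannot be told apart from other causes, since of its genes that were off and also called in moderate drought 538 of 736 (73.1%) were off in the direction of the moderate change, between limits of 95% and 50% that were set after related shares had been seen. Of its genes off higher 30.8% were called higher in moderate drought, fewer than the 39.4% of all tested genes, and of those off lower 31.4% were called lower, more than the 18.9% of all. That test replaced a first one over all genes higher in moderate drought, whose median deviation of −0.0229 in this library, within −0.0771 to 0.121 for the other 8, had argued against a further step but covered many genes outside the pattern, and an outside sample or a different plant state was not tested.

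LOC_Os12g37415 was at 0.2 TPM under normal water and 0.198 TPM in moderate drought, and at 362 TPM in severe drought. Its model lies inside that of LOC_Os12g37410 on the same strand, and reads shared between them are a candidate explanation. The enclosing model was at 330 TPM in moderate and 163 TPM in severe drought, a log2 change of −1.02 ± 0.18 (SE; adjusted p = 0.218 in limma), the direction that an exchange of reads between both models predicts. A change of transcript form in severe drought would give the same values and was not tested.

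In fits of the 6 libraries compared, 1 of 10 splits, the real one, gave as many genes in each comparison. The real split called 13996 genes for moderate drought and the highest other split 0, with 11722 and 1 for severe drought, and 2 and 1 for severe against moderate drought. With 3 libraries against 3 the share cannot be under 0.1, too few splits for a share under 0.05.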

How the results depend on the processing

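The alternatives were fixed before the data were examined, except the median-of-ratios scaling for lists, shared genes and region sets, the shared genes without severe replicate 3, expressed genes as background and regions off the lowest concentration, which were chosen after seeing the data. Causes were not tested unless the setting itself shows them. No called result reversed in the direction of its test. The median of the severe set with lower H2Bub1 changed sign, as given above, but stayed below that of all genes. With a log2 fold threshold of 1, fewer genes pass by construction, 3995 (2510 higher, 1485 lower) in moderate drought, 4479 (2843, 1636) in severe drought and 3442 (2156, 1286) in both. Under all other settings these counts stayed within 1.5 times. For severe against moderate drought the 3 genes became 1 (1 higher, 0 lower) after median-of-ratios scaling, without trend and robust settings and without a filter, and none was lower (0) after quantile normalization, with FPKM, with the fold threshold and in the fit of 6 libraries. With an estimated correlation 0 lists were called in each comparison, against 4, 4 and 1. Leaving out 1 library gave 10226 to 11157 genes in moderate drought (6803 to 7843 higher, 3291 to 3586 lower), 11080 to 13807 in severe drought (7334 to 9162, 3641 to 4645) and 1 to 11 in severe against moderate drought (1 to 6, 0 to 5), with the most without severe replicate 3 in both of the last. Lists called then numbered 4 in every moderate fit, 3 to 5 in severe drought and 0 to 3 in severe against moderate drought, 0 without severe replicate 3 and 3 without severe replicate 2. Shared genes without severe replicate 3 numbered 12645 (8518, 4127).

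With the replicate number as a block, 11781, 12681 and 1 genes were called (1 higher and 0 lower in the last), 10531 were shared, and 3, 3 and 1 lists were called, without the reference genes in moderate (adjusted p = 0.0599) and severe drought (0.0601). The numbers do not pair the libraries. Deviations of 9 same-numbered pairs correlated at −0.257 to 0.143, 2 of them over 0.1, and 2 had their best match in their own number.

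Region pairs shared by the moderate and severe tables fell to 106 with the upper part of each table by fold. The 28 pairs of the moderate and mutant tables became 17 with an overlap of at least 50% of the shorter region, 49 within 1 kb, 9 with the upper part and 71 shared genes. The 12 pairs of the severe and mutant tables became 4, 25, 6 and 34. The upper part by fold holds, by construction, 535 lower moderate, 380 lower severe, 241 higher mutant and 23 lower mutant regions. The 8 genes shared by both mutant tables over expressed genes passed the threshold as fewer than chance. With an estimated correlation, which cannot move medians, the RNA changes of H2Bub1 sets were no longer called, at 1.41 (adjusted p = 0.0984), −0.27 (0.201), 0.42 (0.252) and 0.04 (0.569), and the upper part of the severe higher set gave 0.42 (0.0558). With 1 library left out these medians ranged from 1.35 to 1.47, −0.30 to −0.24, 0.41 to 0.44 and 0.02 to 0.07.

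For the 42 genes named in moderate drought, 609 values under alternatives kept their side of the threshold and direction, 13 lost and 3 gained a call, and 2 moved, both of HUB1 (LOC_Os04g46450), not called, to 0.02 without normal replicate 3 or moderate replicate 2. For the 43 named in severe drought these were 618, 21, 2 and 0. For genes named in severe against moderate drought 99 values stayed and 6 moved, with none called. Depth cannot be read as counts from TPM. Changes of 0.5 on the log2 scale were recovered in 23.9% of simulated genes, in simulations with 200 changed genes at about 5 TPM or more and no outlying library. That share does not carry over to the comparisons with normal water, where far more genes changed and the adjusted threshold is looser.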

Other observations

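The 4 genes of the fixed lists given here failed the expression filter and were highest in severe replicate 3, and were chosen after their values were seen. RAB16D was at 12 TPM there and at 0.676 and 0.315 TPM in severe replicates 1 and 2, LOC_Os07g03710 (listed beforehand as PR1a) at 9.90, 0.525 and 0.222 TPM, LOC_Os01g64000 (listed beforehand as ABI5) at 2.56, 0.564 and 0.423 TPM, and Em at 1.30, 0.122 and 0 TPM. The largest value of RAB16D outside severe drought was 0.359 TPM.

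The RNA of genes with changed H2Bub1 varied little with the place of the region in the authors' deposited table for moderate drought. Genes with higher H2Bub1 within 1 kb of a transcription start had a median RNA log2 fold change of 1.39 (130 genes), those at 1 to 2 kb 1.48 (56 genes) and those at 2 to 3 kb 1.53 (16 genes). Genes with lower H2Bub1 had medians of −0.31 (274 genes), −0.30 (490 genes) and −0.28 (192 genes) at these places. In severe drought the values were 0.52 (62 genes), 0.30 (13 genes) and 0.10 (2 genes) for higher, and 0.08 (199 genes), 0.09 (333 genes) and −0.14 (135 genes) for lower H2Bub1. Differences between places were not tested.

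No set of genes of the mutant table of regions was called in RNA. In moderate drought genes with higher H2Bub1 in the mutant were at 0.18 (383 genes, camera adjusted p = 0.953) and those with lower H2Bub1 at 0.28 (83 genes, adjusted p = 0.553). In severe drought they were at 0.16 (adjusted p = 0.679; percentile 2.56 of random sets matched on expression) and 0.26 (adjusted p = 0.615). The 1023 tested genes of the second of the authors' deposited mutant tables that are not marked as targets were called higher, at 0.26 in moderate (camera adjusted p = 0.025) and 0.29 in severe drought (adjusted p = 0.0423), but not with an estimated correlation (adjusted p = 0.748 and 0.852). The 216 tested genes marked as targets were not called, at 0.17 in moderate (camera adjusted p = 0.953) and 0.19 in severe drought (adjusted p = 0.976). The expression column of the authors' deposited table of 1265 genes correlated across genes at 0.125 with the moderate and at 0.175 with the severe fold changes found here (Pearson; Spearman's rho of 0.0479 and 0.0968), while these correlated at 0.952 (Pearson) with each other over the same 1239 genes. Shifting that column by up to 20 places gave at most 0.0839. Among tested genes 1110 models overlap another on the opposite strand, of which 54.0% changed in moderate drought, and 115 overlap on the same strand, of which 52.2% changed, against 58.6% of the 19417 others.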
